A study of Danio rerio with 8 samples.

How the data were processed

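Caudal fins of 1-year-old Tg(sp7:EGFP) zebrafish, a line whose osteoblast gene promoter drives a green fluorescent protein, were sampled before injury and 1, 2 and 4 days after amputation, with 2 fins per stage and 1 library per fin. Per the labels' protocols, tissue was digested with Accumax, passed through 40 µm strainers and made into libraries with version 2 of the Chromium 3' kit, read with 26 and 75 bases. Per the submitters' processing notes, cutadapt, STAR and Cell Ranger were used, with Cell Ranger defaults, the GRCz10 genome and Ensembl release 91. Tool versions and the rule by which cells were told from empty droplets are not given in the sources used here. The deposited values are raw UMI counts per cell and gene, with no normalization by the authors. They were checked to be whole numbers without repeated cells or genes. The reporter is in the tables as a gene of its own. Raw reads were not used here.

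The 8 libraries held 18788 cells, with medians from 4983 to 9318.5 UMIs per cell. Cells with at least 200 genes and at most 20% mitochondrial counts were kept, 18786 in all. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and a graph of 15 neighbours was clustered with Leiden at resolution 0.5 in scanpy 1.11.5. The 16 clusters became 30 after 3 were split once more, because over 50% of a second class's markers stood out in them. A cluster got a class when at least 3 of that class's markers had a log2 fold of at least 1 over the other cells (prior 10 CPM) and were seen in 10% of its cells, with a lead of 0.25 in mean log2 fold, and when no other class's markers led its top 10 genes. Marker lists were fixed in advance. The naming rule was settled after cluster markers were seen and before any gene was tested. No cluster met the rule for mucosal-like cells, so their share was tested only in the setting that gives each cell its own class. Shares of cells in single libraries carry 95% exact Clopper-Pearson intervals in the tables, and those intervals and the floors cover counting error only.

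Counts were summed per library over the cells of a class, for libraries with at least 20 cells of it. Each class was fitted over all its libraries with edgeR 4.0.16 (R 4.3.3), by quasi-likelihood with stage as the only term, TMM scaling and the filterByExpr filter. Each stage was tested against preinjury, and 4dpa against 1dpa in basal and mesenchymal cells, with Benjamini-Hochberg adjustment over the genes of a contrast and a threshold of 0.05. The difference between basal and superficial responses was an interaction term in a fit of 16 class-by-library sums. Library was a block in that fit, so the 2 classes of a library were paired. The planned hematopoietic contrasts could not be given, because preinjury and 1dpa each kept 1 library. Shares were tested with a two-sided exact permutation test of an F ratio over the 105 ways to split 8 libraries into 4 pairs, adjusted over 5 classes. Groups were taken from the labels, and the groups, tests, gene lists, fixed genes and most other settings tried were chosen before the data were examined.

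The 18 gene lists were immediate early and heat shock genes, the unfolded protein and secretory pathway, fibrillar and provisional matrix, matrix proteases and inhibitors, osteoblast and mineralisation genes, blastema and fin outgrowth signalling, keratins, epithelial junctions and hemidesmosomes, actin cytoskeleton and migration, inflammatory mediators, interferon response, antigen presentation by MHC class II, glycolysis, nuclear oxidative phosphorylation, mitochondrial genome transcripts, ribosome biogenesis, S phase and G2/M phase. They were written from general knowledge and tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over 252 tests, and again with an estimated correlation and with fry. A list needed at least 5 tested genes.

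Genes were named by a fixed rule: in each class and contrast, the 4 highest and 4 lowest log2 fold changes among genes past the threshold whose libraries did not overlap between stages and which reached 50 CPM in the higher stage. Up to 4 members with the lowest adjusted p of a list could be named as well, and 29 genes were fixed in advance, of which 27 matched 31 IDs (mpx and mpeg1.1 did not). Clone-like symbols, mitochondrial and hemoglobin genes were passed over, and the prefixes that mark clone names also passed over CTSK and ALDH1A3. The same rule was applied to the interaction with a prior of 1 CPM. A log2 difference is left out where a class had 0 counts at a stage. Symbols are those of the name table, where many zebrafish genes carry human-style capitals. Where a symbol is shared by several IDs, the ID is given at its first mention, except for list members: BMP2 is ENSDARG00000013409, COL12A1 ENSDARG00000078322, ENO1 ENSDARG00000022456, ALDOC ENSDARG00000019702, MCM6 ENSDARG00000057683, PKM ENSDARG00000099730, RRM2 ENSDARG00000078069 and VIM ENSDARG00000010008. The gene fixed as tph1b matched TPH2, while TPH1 came in by the rule.

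Other settings chosen in advance were DESeq2 1.42.0, RLE size factors, no expression filter, the fin number as a block, the lane as a covariate, a stricter cell filter (500 genes, 10% mitochondrial), removal of 112 doublets called by scrublet, Leiden resolution 1.0, a class per cell, and leaving out each library. Settings chosen after seeing the data were clusters not split again, clusters led by another class's markers kept in their best class, top genes ranked by the naming fold, a fit without the 1dpa libraries, and hematopoietic cells at 4dpa against 2dpa. Per the labels, the 2 libraries of 1dpa shared lane 2 and elsewhere the fin number was the lane, so stage was tested with the lane as a covariate. Within a lane most stages had 1 library, which allows no test, and the direction of called genes was compared there in the libraries they were called from, which favours the same direction. The tests were run on simulated data with 200 genes changed, evenly up and down, in 1 stage. There, 0.0196 to 0.166% of unchanged genes were called, and 54 to 94% of genes raised 4-fold and 6 to 36% of genes raised 2-fold were recovered, and 34.1 to 74.5% of genes lowered 4-fold. In the real data 11.2 to 54.0% of genes were called against preinjury, so the simulated rates need not hold for them. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.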

Results

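Single-cell transcript counts were compared between uninjured caudal fins of Tg(sp7:EGFP) zebrafish (preinjury) and fins 1, 2 or 4 days after amputation (1dpa, 2dpa and 4dpa), with 2 fins per stage. The 8 libraries held 341 to 4261 cells and from 2411266 (1dpa fin 1) to 43621774 (2dpa fin 2) unique molecular identifiers (UMIs). Levels are CPM (counts of a gene scaled to the library size) from counts summed over a cell class, given as the mean ± SD of 2 libraries. Changes are edgeR log2 fold changes ± standard error against preinjury unless another stage is named. Genes are said to rise or fall only where the adjusted p was under 0.05. Where a stage had 0 counts, the "at least" fold is the other stage's mean over a floor of 3 counts in the group. This fold ignores the spread between libraries. Where the other stage lay under that floor, only the counts are given. Where a stage had 1 to 3 counts, the count ratio is the other stage's mean over its pooled level. The 95% interval covers those counts alone. Near-identical gene copies, such as ptgdsb.1 and ptgdsb.2 or the hsp70 genes, can take each other's reads, so their separate values are uncertain. Nothing in the labels says that the 2 fins of a stage came from separate fish, so p-values measure only the spread between libraries.

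Cells fell into 5 named classes: superficial, intermediate and basal epithelial, mesenchymal and hematopoietic. Superficial cells made up 29.03 ± 1.72% of preinjury cells, and 32.6 ± 19.6%, 4.81 ± 0.7003% and 12.5 ± 6.43% at 1, 2 and 4dpa. Mesenchymal cells went from 6.92 ± 2.23% to 15.8 ± 3.69% at 4dpa, and hematopoietic cells from 0.985 ± 1.29% to 6.87 ± 0.684%. Basal cells stood at 34.5 ± 3.57% before injury and 21.4 ± 6.35% at 4dpa, and intermediate cells at 28.2 ± 4.37% and 28.9 ± 4.32%. The preinjury intermediate name rests on cluster 0, with 3 of 11 markers up, which gets no name at resolution 1.0. With a class per cell, the preinjury libraries held 10 and 1 intermediate and 13 and 6 mesenchymal cells. The log2 ratio of regenerating to preinjury shares then went from -0.11 to 6.87 and from 0.68 to 4.45. In exact permutation tests over the 4 stages (two-sided, n = 2 libraries per stage, smallest possible p = 0.00952) no class passed. The unadjusted p was 0.0476 for superficial, 0.0952 for intermediate, 0.305 for basal, 0.0667 for mesenchymal and 0.0286 for hematopoietic cells in these exact tests. Benjamini-Hochberg adjusted p in the exact tests was 0.111 for superficial, mesenchymal and hematopoietic, 0.119 for intermediate and 0.305 for basal cells. Cells of clusters that met no naming rule made up 0.318, 17.6, 5.27 and 14.4% at preinjury, 1, 2 and 4dpa. With the unnamed cluster 10, which has 11 of 16 basal markers up, basal cells would make up 31.5% at 4dpa. The unnamed cluster 15.1 of 1dpa has 8 of 16 basal and 7 of 11 intermediate markers up, at nearly equal mean folds, and could be either. EGFP, the reporter driven by the osteoblast gene sp7, was highest in superficial epithelial cells of all 8 libraries, at 214 ± 101 CPM against 17.9 ± 14.0 CPM in mesenchymal cells. The mesenchymal class takes in osteoblasts along with other stromal cells, so its mean is not the level of osteoblasts. An EGFP UMI was held by 11.9% of mesenchymal and 55.9% of superficial cells. The sequence that EGFP counts were matched to is not given in the sources used here, so reads from other transcripts among them cannot be excluded.

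**Figure D1:**
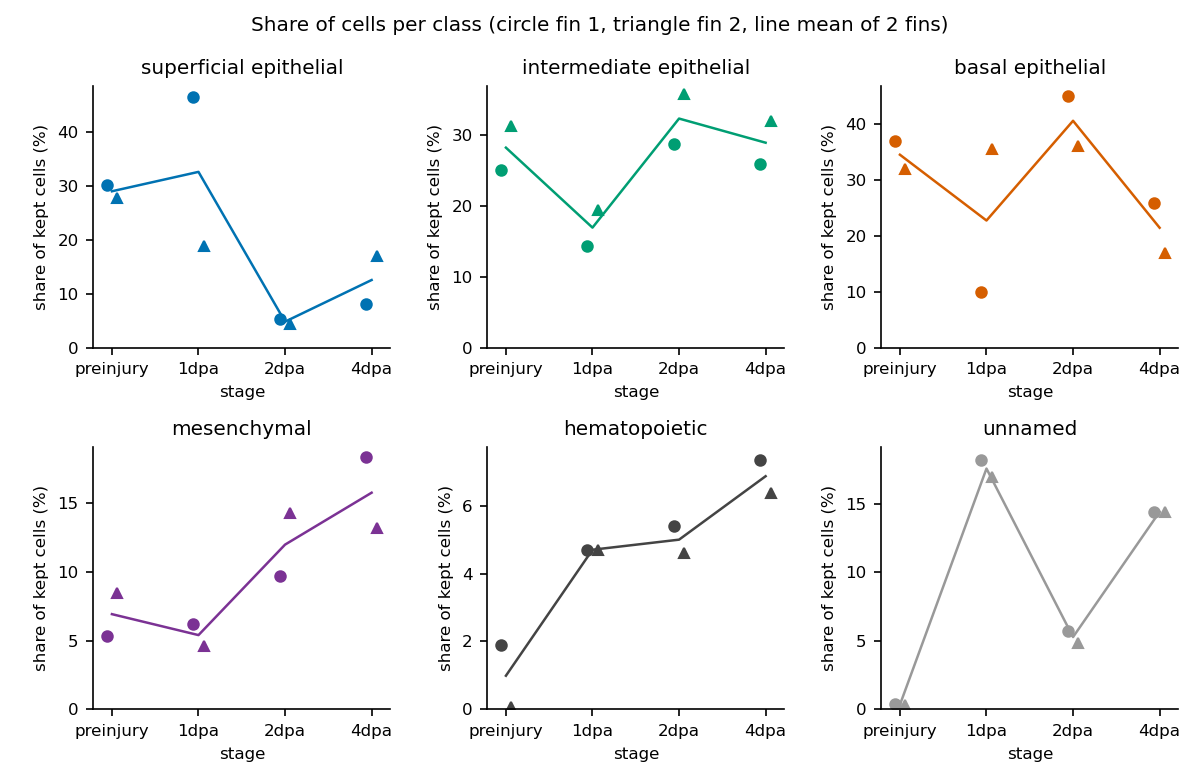
Share of kept cells (percent, from 0) per class and stage, with circles for fin 1, triangles for fin 2 and lines through the mean of 2 fins. Superficial cells drop to 4.81% at 2dpa, and mesenchymal cells reach 15.8% at 4dpa.

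In superficial epithelial cells krt18a.1, a keratin of simple epithelia, rose from 50.9 ± 18.1 to 6960.4 ± 3610.4 CPM (log2 fold change 7.11 ± 0.45, adjusted p = 3.89e-05) at 1dpa. krt93, another keratin gene, rose from 274 ± 11.4 to 5488 ± 69.7 CPM (log2 fold change 4.32 ± 0.19, adjusted p = 3.12e-06). The inducible chaperone gene hsp70.1 rose from 3.12 ± 1.27 to 78.3 ± 21.9 CPM (log2 fold change 4.74 ± 0.43, adjusted p = 0.000283), and S1PR5, a receptor for the lipid signal sphingosine-1-phosphate, from 3.73 ± 0.804 to 55.9 ± 15.8 CPM (log2 fold change 3.87 ± 0.34, adjusted p = 0.0002705). ptgdsb.1, a lipocalin-type prostaglandin synthase, fell from 764 ± 622 to 0 CPM (at least 897-fold lower, adjusted p = 0.0003804), and its neighbour ptgdsb.2 from 168 to 0.222 CPM (count ratio 593, interval 107 to 23441). RBP4, the carrier of retinol, fell from 111 to 0.222 CPM (count ratio 393, interval 70.5 to 15511), and the chemokine gene ccl25b from 64.6 to 0.222 CPM (count ratio 228, interval 40.8 to 8986). Of 8045 genes tested, 413 rose and 491 fell at 1dpa, 694 and 682 at 2dpa, and 761 and 812 at 4dpa.

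At 2dpa COL10A1 (ENSDARG00000054753), a collagen of hypertrophic cartilage and fish bone, rose in superficial cells from 0 to 56.2 ± 69.9 CPM (at least 201-fold higher, adjusted p = 0.00840). enam, an enamel-type matrix gene, rose from 0.0693 ± 0.09798 to 97.5 ± 92.3 CPM (count ratio 1043, interval 187 to 41212, adjusted p = 0.000665). In hematopoietic cells of 2dpa, where neither gene has a known role, COL10A1 read 5.81 CPM and enam 29.1 CPM. The coagulation factor gene f5 rose from 0.139 to 50.3 CPM (count ratio 269, interval 74.5 to 2222) and CYGB, a globin that handles oxygen and nitric oxide, from 0.208 to 52.4 CPM (count ratio 187, interval 63.97 to 906), with 101 CPM of CYGB in hematopoietic cells. ptgdsb.2 fell from 168 to 0 CPM (at least 188-fold lower), the keratin gene krt99 from 231 to 0.289 CPM (count ratio 771, interval 138 to 30470.2), RBP4 from 111 to 0.289 CPM (count ratio 373, interval 66.9 to 14728) and the gel-forming mucin muc5.2 from 69.7 to 0.289 CPM (count ratio 233, interval 41.8 to 9205). At 4dpa COL10A1 rose from 0 to 155 CPM (at least 551-fold higher) and enam from 0.0693 to 498 CPM (count ratio 5331, interval 957 to 210562), beside 249 and 852 CPM in hematopoietic cells. and1, an actinodin of the fin fold's unmineralised rays, rose from 0 to 87.5 CPM (at least 312-fold higher) where hematopoietic cells read 170.4 CPM. ntrnl2 rose from 1.49 ± 1.13 to 59.0 ± 1.12 CPM (log2 fold change 5.49 ± 0.63, adjusted p = 0.000459). ptgdsb.2 fell from 168 to 2.35 CPM (log2 fold change -6.11 ± 0.57), ptgdsb.1 from 764 to 13.5 CPM (log2 fold change -5.83 ± 0.62), RBP4 from 111 to 3.32 CPM (log2 fold change -5.14 ± 0.49) and the chemokine gene ccl27b from 50.4 to 1.58 CPM (log2 fold change -4.99 ± 0.34).

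Genes fixed before the data were examined are given whatever their value, with log2 fold changes ± standard error for 1, 2 and 4dpa in parentheses. In superficial cells the surface keratin krt4 fell at 2 and 4dpa, from 18250.2 CPM to 8382 and 8521 CPM (0.66 ± 0.24, -1.12 ± 0.25 and -1.099 ± 0.25). The basal keratin krt1-19e (krtt1c19e) fell at each stage, from 181 CPM to 13.02 CPM at 1dpa (-3.83 ± 0.33, -4.65 ± 0.36 and -3.67 ± 0.31). il1b, an early inflammatory cytokine, rose at each stage, from 1.26 to 13.8 CPM at 1dpa (3.39 ± 0.55, 3.05 ± 0.57 and 3.32 ± 0.53). TP63, the regulator of stratified epithelium, fell at 1dpa and rose later (-1.61 ± 0.25, 1.79 ± 0.22 and 0.81 ± 0.22). epcam fell at 4dpa (-0.20 ± 0.18, -0.49 ± 0.18 and -0.78 ± 0.18), and cdh1 did not pass (0.58 ± 0.22, 0.52 ± 0.22 and 0.50 ± 0.22). The fibronectin gene FN1 (ENSDARG00000006526) rose (1.85 ± 0.43, 3.29 ± 0.44 and 2.60 ± 0.43), and FN1 (ENSDARG00000019815) did so at 1 and 2dpa (3.82 ± 0.80, 3.46 ± 0.82 and 2.58 ± 0.83). col1a1a rose at 2 and 4dpa (-0.74 ± 0.69, 3.81 ± 0.53 and 4.12 ± 0.53), to 139 CPM, beside 298 CPM in hematopoietic cells. JUNB (ENSDARG00000074378), an immediate early gene, fell (-0.72 ± 0.20, -1.09 ± 0.20 and -1.11 ± 0.20), and JUNB (ENSDARG00000104773) fell at 2 and 4dpa (-0.27 ± 0.26, -1.88 ± 0.27 and -2.06 ± 0.27). mmp13a rose at 4dpa (1.42 ± 0.85, 2.15 ± 0.79 and 3.36 ± 0.66). AGR2, a mucous-cell gene, did not pass (0.41 ± 0.81, -3.23 ± 1.06 and -0.64 ± 0.82), and neither did PCNA (-0.08 ± 0.33, -0.41 ± 0.34 and -0.19 ± 0.31). WNT5A, TNC (ENSDARG00000021948) and and2 rose at 2 and 4dpa, to 3.88, 3.59 and 25.99 CPM at 4dpa. LEF1, msx1b, MMP9 and mki67 were not tested and read 1.82, 4.13, 4.01 and 4.08 CPM at 4dpa.

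Of immediate early and heat shock genes in superficial cells 4, 0 and 0 of 31 members rose and 3, 22 and 24 fell at 1, 2 and 4dpa (4, 1 and 0 rose and 5, 24 and 25 fell adjusted over the list alone), with camera adjusted p = 0.998, 6.38e-14 and 7.51e-15, and adjusted p = 0.999, 0.257 and 0.257 with an estimated correlation. FOS, a marker of acute activation, fell at 2dpa with others: FOS (-2.77 ± 0.29), FOSL1 (-2.08 ± 0.24), mcl1a (-1.64 ± 0.19) and NR4A1 (-2.36 ± 0.28). At 1dpa chaperone genes of the list rose, hsp70.3 (3.19 ± 0.29), dnajb1b (1.101 ± 0.17) and hsp70l (1.72 ± 0.31). In the unfolded protein and secretory pathway, which folds proteins for export, 14, 19 and 22 of 37 members rose and 1, 5 and 5 fell at 1, 2 and 4dpa (21, 19 and 24 rose and 1, 5 and 5 fell adjusted over the list alone), with camera adjusted p = 2.32e-07, 1.26e-06 and 1.25e-09, and adjusted p = 0.240, 0.240 and 0.237 with an estimated correlation. Its leading members at 4dpa were MANF (2.42 ± 0.20), PDIA6 (2.40 ± 0.24), calr3b (3.41 ± 0.30) and PDIA4 (2.81 ± 0.28). In the fibrillar and provisional matrix 2, 12 and 12 of 15 members rose at 1, 2 and 4dpa (2, 14 and 14 adjusted over the list alone), with camera adjusted p = 0.607, 1.11e-08 and 4.79e-08, and adjusted p = 0.896, 0.392 and 0.403 with an estimated correlation. Of nuclear oxidative phosphorylation genes at 4dpa, 15 of 54 members rose (17 adjusted over the list alone), with camera adjusted p = 1.76e-07, and adjusted p = 0.426 with an estimated correlation. cox6b1 (1.24 ± 0.20) and cox5aa (0.80 ± 0.17) rose. Of ribosome biogenesis genes at 1dpa, 8 of 24 members fell (13 adjusted over the list alone), with camera adjusted p = 7.59e-07, and adjusted p = 0.257 with an estimated correlation. nop53 (-1.93 ± 0.29) and DDX21 (-1.82 ± 0.36) fell. Of mitochondrial genome transcripts at 1dpa, 3 of 13 members rose (3 adjusted over the list alone), with camera adjusted p = 0.00147, and adjusted p = 0.431 with an estimated correlation. Of osteoblast and mineralisation genes at 1dpa, 1 of 5 members fell (4 adjusted over the list alone), with camera adjusted p = 0.0202, and adjusted p = 0.331 with an estimated correlation, with the calcification inhibitor mgp (-2.72 ± 0.57).

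The superficial counts rest on few cells, from 158 to 894 per library. Without preinjury fin 2, 1dpa fin 1 or 1dpa fin 2, 488, 320 or 310 genes were called at 1dpa, and without the low-count filter 527 rose and 870 fell. At 2dpa 774, 516 or 405 were called without preinjury fin 2, 2dpa fin 1 or 2dpa fin 2, and at 4dpa 948 or 897 without preinjury fin 2 or 4dpa fin 1. With clusters not split again, a test chosen after seeing the data, 1114 rose and 1115 fell at 2dpa. Within single lanes at least 99.9% of called genes kept their direction, in the libraries they were called from. The cells came from different clusters by stage, with 99.4% of preinjury cells in cluster 4 and 95.3% of 1dpa cells in cluster 5.

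In intermediate epithelial cells cxl34c, a chemokine-like gene, rose from 0 to 196 ± 45.6 CPM (at least 695-fold higher, adjusted p = 7.62e-07) at 1dpa. fabp4a, a fatty acid carrier, rose from 0.135 ± 0.1904 to 533 ± 89.3 CPM (count ratio 5677, interval 1019 to 224226, adjusted p = 3.81e-07), where hematopoietic cells read 2076 CPM at 2dpa. adam8a, a sheddase of motile cells, rose from 0.0721 ± 0.102 to 301 ± 15.9 CPM (count ratio 3210.2, interval 576 to 126794, adjusted p = 6.93e-07) and CYGB from 0.135 to 175 CPM (count ratio 1867, interval 335 to 73750.1). gsdf, a TGF-beta family ligand, fell from 61.8 ± 39.04 to 0 CPM (at least 53.8-fold lower, adjusted p = 0.000277), and cfd, the complement activator, from 2464 ± 14.1 to 9.28 ± 5.53 CPM (log2 fold change -8.47 ± 0.55, adjusted p = 1.32e-06). ptgdsb.1 fell from 561 to 0.896 CPM (log2 fold change -8.52 ± 0.52) and ptgdsb.2 from 131 to 0.672 CPM (count ratio 114, interval 39.1 to 555). Of 11477 genes tested, 1072 rose and 1170 fell at 1dpa, 2168 and 2207 at 2dpa, and 1930 and 1780 at 4dpa.

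At 2dpa cxl34c rose in intermediate cells from 0 to 409 CPM (at least 1453-fold higher), CYGB from 0.135 to 1133 CPM (count ratio 12069, interval 2166 to 476698) and adam8a from 0.0721 to 419 CPM (count ratio 4466, interval 802 to 176411). Hematopoietic cells read 101 CPM of CYGB and 89.1 CPM of adam8a. and1 rose from 0 to 63.4 CPM (at least 225-fold higher), where hematopoietic cells read 65.6 CPM. tnfrsf11b, the decoy receptor that restrains osteoclasts, fell from 1131 ± 35.7 to 1.81 ± 1.04 CPM (log2 fold change -9.21 ± 0.63, adjusted p = 1.16e-06). cfd fell from 2464 to 4.79 CPM (log2 fold change -9.04 ± 0.50), ccl27b from 247 to 0.5599 CPM (log2 fold change -8.80 ± 0.45) and RBP4 from 530.5 to 3.89 CPM (log2 fold change -7.12 ± 0.42). At 4dpa cxl34c rose from 0 to 294 CPM (at least 1045-fold higher) and CYGB from 0.135 to 329 CPM (count ratio 3499, interval 628 to 138212). and1 rose from 0 to 106 CPM (at least 377-fold higher) and COL10A1 from 0 to 69.9 CPM (at least 248-fold higher), with 170.4 and 249 CPM in hematopoietic cells. fabp1b.2, an intestinal-type fatty acid carrier, fell from 268 to 0.0524 CPM (count ratio 5174, interval 929 to 204344), and HSD17B7, a cholesterol synthesis enzyme, from 514 ± 299 to 9.93 ± 4.72 CPM (log2 fold change -5.69 ± 0.47, adjusted p = 8.12e-06). RBP4 fell from 530.5 to 6.14 CPM (log2 fold change -6.43 ± 0.41) and tnfrsf11b from 1131 to 18.4 CPM (log2 fold change -5.94 ± 0.53).

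Of the fixed genes, given whatever their value, krt4 rose at each stage in intermediate cells, from 562 CPM to 31131, 10846 and 2684 CPM (log2 fold changes 5.79 ± 0.35, 4.27 ± 0.32 and 2.26 ± 0.30), and krt1-19e fell, from 374 CPM to 2.91, 4.42 and 82.1 CPM (log2 fold changes -6.29 ± 0.51, -6.40 ± 0.42 and -2.18 ± 0.34). FN1 (ENSDARG00000006526) rose, from 43.9 CPM to 2968, 2815 and 1572 CPM (log2 fold changes 6.06 ± 0.42, 5.99 ± 0.42 and 5.15 ± 0.40), as did FN1 (ENSDARG00000019815) (4.02 ± 0.62, 3.22 ± 0.56 and 2.36 ± 0.59). The collagenase mmp13a rose, from 0.6201 CPM to 68.2, 29.5 and 15.6 CPM (log2 fold changes 7.14 ± 0.91, 5.65 ± 0.91 and 4.74 ± 0.95), and so did il1b (2.84 ± 0.70, 3.78 ± 0.56 and 4.64 ± 0.55). WNT5A, a morphogen of outgrowth, rose at 2 and 4dpa (0.46 ± 1.24, 3.83 ± 0.53 and 3.68 ± 0.54), and so did col1a1a (0.50 ± 0.42, 4.81 ± 0.30 and 4.65 ± 0.30). JUNB fell in its ENSDARG00000074378 (-1.24 ± 0.23, -2.16 ± 0.24 and -1.43 ± 0.23) and ENSDARG00000104773 copies (-1.44 ± 0.25, -2.24 ± 0.25 and -1.68 ± 0.24). epcam fell (-0.72 ± 0.20, -0.98 ± 0.20 and -1.38 ± 0.21), while cdh1 did not pass (-0.04 ± 0.24, -0.19 ± 0.24 and -0.19 ± 0.24). TP63 rose at 2dpa (-0.18 ± 0.23, 0.82 ± 0.22 and -0.04 ± 0.22), and AGR2 fell at 2dpa (2.24 ± 1.03, -4.88 ± 1.24 and -2.70 ± 1.08). mki67, a proliferation marker, rose at 4dpa (0.70 ± 0.62, 0.34 ± 0.47 and 1.88 ± 0.46), as did msx1b (1.19 ± 0.62, 0.07 ± 0.47 and 1.30 ± 0.45), and PCNA did not pass (-0.10 ± 0.30, -0.52 ± 0.26 and 0.47 ± 0.26). MMP9 rose at 2dpa (1.11 ± 1.00, 2.51 ± 0.60 and 1.67 ± 0.64). LEF1, TNC (ENSDARG00000021948) and and2 rose at 2 and 4dpa, to 1.45, 2.81 and 20.7 CPM at 4dpa, and ALDH1A2 did not pass, at 0.833 CPM.

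Of the lists in intermediate cells, immediate early and heat shock genes fell in the later stages: 5, 3 and 2 of 33 members rose and 14, 28 and 29 fell at 1, 2 and 4dpa (6, 3 and 3 rose and 15, 28 and 29 fell adjusted over the list alone), with camera adjusted p = 0.185, 9.49e-12 and 3.68e-12, and adjusted p = 0.769, 0.3697 and 0.3697 with an estimated correlation. Members at 2dpa were FOSL1 (-3.36 ± 0.25), FOS (-3.57 ± 0.31), ATF3 (-3.74 ± 0.33) and FOSB (-2.83 ± 0.25). Interferon response genes rose at 2 and 4dpa: 3, 20 and 23 of 34 members rose and 6, 2 and 2 fell at 1, 2 and 4dpa (3, 21 and 25 rose and 6, 3 and 3 fell adjusted over the list alone), with camera adjusted p = 0.312, 0.000289 and 4.71e-08, and adjusted p = 0.8005, 0.488 and 0.392 with an estimated correlation. IRF7 (3.52 ± 0.30), mxb (6.52 ± 0.51) and gbp1 (2.88 ± 0.29) rose at 4dpa. In ribosome biogenesis at 2dpa 23 of 28 members fell (24 adjusted over the list alone), with camera adjusted p = 1.91e-09, and adjusted p = 0.423 with an estimated correlation. RRS1 (-3.28 ± 0.27), DDX21 (-2.78 ± 0.26) and nop2 (-2.19 ± 0.26) fell. In the fibrillar matrix at 2dpa 18 of 21 members rose (19 adjusted over the list alone), with camera adjusted p = 1.01e-10, and adjusted p = 0.3804 with an estimated correlation, among them SPARC at 749 CPM against 383 CPM in hematopoietic cells. Of keratins at 1dpa 11 of 20 members rose and 5 fell (11 and 5 adjusted over the list alone), with camera adjusted p = 0.004405, and adjusted p = 0.447 with an estimated correlation, among them krt18a.1 (9.36 ± 0.50) and krt93 (5.72 ± 0.35) up and krt15 (-4.22 ± 0.32) down. G2/M phase genes, which drive mitosis, came up at 4dpa, when 27 of 30 members rose (28 adjusted over the list alone), with camera adjusted p = 2.89e-10, and adjusted p = 0.403 with an estimated correlation, as plk1 (3.44 ± 0.48) and CKS1B (2.08 ± 0.33) show. In blastema and fin outgrowth signalling at 2dpa 14 of 32 members rose and 4 fell (15 and 4 adjusted over the list alone), with camera adjusted p = 0.0139, and adjusted p = 0.518 with an estimated correlation. dlx4a (5.69 ± 0.33) and BMP2 (4.68 ± 0.29) rose. Inflammatory mediators fell at 2dpa, when 7 of 31 members rose and 17 fell (7 and 18 adjusted over the list alone), with camera adjusted p = 0.000742, and adjusted p = 0.2997 with an estimated correlation. CXCL12 (-4.05 ± 0.32), cxcl18b (-3.64 ± 0.29) and ccl25b (-4.25 ± 0.36) fell.

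In intermediate cells 1 library decided 2 counts, since 621 genes were called at 1dpa without 1dpa fin 2, and 2822 at 2dpa without 2dpa fin 2. At least 99.7% of called genes kept their direction within single lanes. All changes against preinjury here rest on the name of cluster 0, and no intermediate value remains at resolution 1.0. Cluster 15.3, with 27.0% of the 1dpa cells, loses its name when its top genes are ranked by the fold used for naming. Clusters changed with stage, from 98.97% of preinjury cells in cluster 0 to 93.3% of 2dpa cells in cluster 12.

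In basal epithelial cells krt1-19e, a basal keratin, fell from 14185 ± 3752 to 6.32 ± 2.97 CPM (log2 fold change -10.79 ± 0.51, adjusted p = 9.80e-09) at 1dpa. tmsb2, a thymosin that binds actin monomers, rose from 0 to 156 ± 35.5 CPM (at least 367-fold higher, adjusted p = 5.99e-06). vcana, a versican of provisional matrix, rose from 0 to 92.9 ± 41.98 CPM (at least 219-fold higher, adjusted p = 4.28e-08) and tubb5, a tubulin, from 0.0953 ± 0.135 to 285 ± 57.99 CPM (count ratio 2015, interval 362 to 79584, adjusted p = 3.67e-09). fabp4a rose from 0.286 to 1957 CPM (count ratio 4606, interval 1576 to 22334), where hematopoietic cells read 2076 CPM at 2dpa. soul5, a heme-binding gene, fell from 113 to 0 CPM (at least 152-fold lower), the serine protease htra4 from 84.3 to 0 CPM (at least 113-fold lower) and the chemokine ccl19b from 52.8 to 0 CPM (at least 71.1-fold lower). Of 11057 genes tested, 1678 rose and 2923 fell at 1dpa, 2716 and 3256 at 2dpa, and 2549 and 2742 at 4dpa. The median log2 fold change of all genes was -0.30 at 1dpa, and without the expression filter 49.1% of 4631 called genes were higher against 36.5% with it. At 2 and 4dpa it was 51.7% of 6880 and 54.1% of 5670 without it.

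Basal values at 2dpa rest on cluster 13, which holds 98.7% of these cells and has 11 of 16 basal markers up but 0 among its top 10 genes. With those genes ranked by the fold used for naming it has 0 basal markers and 1 of another class, loses its name, and no basal value at 2dpa remains. and1 rose at 2dpa in basal cells from 0.275 ± 0.3895 to 1085 ± 94.6 CPM (count ratio 7657, interval 1374 to 302420, adjusted p = 9.69e-10), above the 65.6 CPM of hematopoietic cells. COL10A1 rose from 0 to 156 ± 25.8 CPM (at least 367-fold higher, adjusted p = 2.70e-07), emilin1b, an elastic fibre gene, from 0 to 121 ± 6.76 CPM (at least 285-fold higher, adjusted p = 1.10e-08), and FREM3, a basement membrane gene, from 0 to 117 CPM (at least 275-fold higher). cfd fell from 9424 ± 21.1 to 0.892 ± 0.326 CPM (log2 fold change -13.34 ± 0.78, adjusted p = 9.10e-09), krt1-19e from 14185 to 3.68 CPM (log2 fold change -11.91 ± 0.49), ccl27b from 1269.8 to 0.669 CPM (log2 fold change -10.85 ± 0.44) and the neutrophil chemokine cxcl8b.1 from 1708 to 1.26 CPM (log2 fold change -10.38 ± 0.71). At 4dpa COL10A1 rose from 0 to 924 CPM (at least 2174-fold higher), enam from 0.0953 to 3619 CPM (count ratio 25549, interval 4585 to 1009120), and1 from 0.275 to 1799.6 CPM (count ratio 12704, interval 2280.1 to 501774) and scpp7, a secretory calcium-binding phosphoprotein, from 0 to 131 CPM (at least 308-fold higher). Hematopoietic cells of 4dpa read 249 CPM of COL10A1, 852 of enam, 170.4 of and1 and 45.9 of scpp7. fabp1b.2 fell from 94.7 to 0 CPM (at least 355-fold lower), TIMP4 (ENSDARG00000100795), a protease inhibitor, from 516 to 2.502 CPM (log2 fold change -7.85 ± 0.38), fam169aa from 92.4 to 0.464 CPM (log2 fold change -7.64 ± 0.36) and soul5 from 113 to 0.724 CPM (log2 fold change -7.42 ± 0.40).

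Among the fixed genes, given whatever their value, krt4 rose in basal cells at each stage, from 281 CPM to 17043, 7264 and 6275 CPM (log2 fold changes 5.93 ± 0.33, 4.69 ± 0.31 and 4.48 ± 0.31). LEF1, the nuclear partner of Wnt signalling, rose, from 0.0953 CPM to 40.1, 51.9 and 40.2 CPM (count ratio 283, interval 50.9 to 11192, count ratio 366, interval 65.7 to 14458 and count ratio 284, interval 50.9 to 11209). WNT5A rose, from 1.86 CPM to 21.99, 35.6 and 27.7 CPM (log2 fold changes 2.87 ± 0.51, 4.36 ± 0.39 and 4.00 ± 0.40), and MMP9, a gelatinase, from 2.53 CPM to 24.1, 45.6 and 40.1 CPM (log2 fold changes 3.58 ± 0.46, 4.08 ± 0.40 and 3.93 ± 0.41). FN1 (ENSDARG00000019815) rose, from 20.2 CPM to 1378, 293 and 197 CPM (log2 fold changes 6.15 ± 0.29, 3.90 ± 0.27 and 3.33 ± 0.27), as did FN1 (ENSDARG00000006526) (1.52 ± 0.25, 1.29 ± 0.25 and 1.30 ± 0.25) and TNC (ENSDARG00000021948) (3.28 ± 0.77, 3.18 ± 0.65 and 2.35 ± 0.73). col1a1a rose at 2 and 4dpa (0.60 ± 0.24, 3.30 ± 0.26 and 3.12 ± 0.26), and so did and2 and TNC (ENSDARG00000078362), to 19.8 and 4.52 CPM at 4dpa. mki67 rose at 1 and 4dpa and fell at 2dpa (2.09 ± 0.39, -1.14 ± 0.42 and 3.82 ± 0.30), and PCNA fell at 1 and 2dpa (-0.97 ± 0.23, -2.57 ± 0.20 and -0.42 ± 0.19). Of the epithelial genes TP63 (-0.79 ± 0.25, -0.65 ± 0.24 and -0.71 ± 0.24), cdh1 (-0.89 ± 0.20, -1.05 ± 0.19 and -0.50 ± 0.19) and epcam (-1.08 ± 0.23, -1.62 ± 0.23 and -1.57 ± 0.23) fell. JUNB fell in its ENSDARG00000074378 (-2.13 ± 0.34, -2.69 ± 0.35 and -1.84 ± 0.34) and ENSDARG00000104773 copies (-3.28 ± 0.41, -3.30 ± 0.39 and -2.40 ± 0.38). AGR2 rose at 1dpa and fell later (3.09 ± 0.75, -3.99 ± 0.89 and -3.37 ± 0.99). il1b rose at 4dpa (-0.64 ± 0.72, -0.58 ± 0.50 and 2.67 ± 0.42), msx1b at 1 and 4dpa (3.09 ± 0.51, 1.22 ± 0.50 and 1.48 ± 0.52), and mmp13a at 2dpa (0.55 ± 0.33, 1.05 ± 0.29 and -0.58 ± 0.31). SHH (ENSDARG00000068567), a morphogen of ray branching, rose at 2 and 4dpa and FGF20 (ENSDARG00000086070), a growth factor of blastema formation, at 4dpa, to 2.19 and 3.14 CPM. In other classes these genes, and in all classes SHH (ENSDARG00000038867) and FGF20 (ENSDARG00000007356), were not tested. SP7, tnfa, TPH2 and ALDH1A2 read 0, 0.797, 0.328 and 0.536 CPM in basal cells at 4dpa, and mpx and mpeg1.1 matched no gene.

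Of ribosome biogenesis genes in basal cells 16, 27 and 24 of 27 members fell at 1, 2 and 4dpa (16, 27 and 24 adjusted over the list alone), with camera adjusted p = 2.02e-05, 8.46e-11 and 9.11e-09, and adjusted p = 0.524, 0.392 and 0.423 with an estimated correlation. Its members at 2dpa included RRS1 (-4.46 ± 0.29), nop2 (-3.61 ± 0.26) and GNL3 (-3.34 ± 0.25). In the fibrillar and provisional matrix 11, 20 and 23 of 24 members rose and 5, 1 and 1 fell at 1, 2 and 4dpa (12, 21 and 23 rose and 5, 1 and 1 fell adjusted over the list alone), with camera adjusted p = 0.00105, 4.79e-08 and 1.18e-11, and adjusted p = 0.257, 0.237 and 0.237 with an estimated correlation. COL12A1 (6.33 ± 0.26) and COL11A1 (3.27 ± 0.23) rose at 4dpa, and DCN stood at 266 CPM against 17.3 CPM in hematopoietic cells. In the secretory pathway at 1dpa 28 of 37 members rose and 4 fell (28 and 4 adjusted over the list alone), with camera adjusted p = 8.30e-11, and adjusted p = 0.269 with an estimated correlation. PDIA6 (3.45 ± 0.21), SDF2L1 (3.31 ± 0.25) and HYOU1 (2.81 ± 0.22) rose. Of matrix proteases and inhibitors at 1dpa 11 of 19 members rose and 3 fell (13 and 3 adjusted over the list alone), with camera adjusted p = 0.001599, and adjusted p = 0.431 with an estimated correlation, with adam8a (8.80 ± 0.37) up and mmp30 (-4.27 ± 0.26) down. In blastema and fin outgrowth signalling at 4dpa 20 of 33 members rose and 4 fell (20 and 5 adjusted over the list alone), with camera adjusted p = 0.000448, and adjusted p = 0.295 with an estimated correlation. BMP2 (count ratio 66.7, interval 18.5 to 550.5) and jag1a (3.18 ± 0.27) rose. S phase genes fell at 2dpa, when 0 of 25 members rose and 23 fell (1 and 24 adjusted over the list alone), with camera adjusted p = 4.02e-07, and adjusted p = 0.3697 with an estimated correlation. MCM5 (-4.33 ± 0.35) and MCM6 (-3.44 ± 0.27) fell. G2/M phase genes rose at 4dpa, when 28 of 30 members rose (29 adjusted over the list alone), with camera adjusted p = 3.55e-10, and adjusted p = 0.431 with an estimated correlation. CCNB1 (count ratio 70.7, interval 24.2 to 343) and CDC20 (4.74 ± 0.56) rose. Junction and hemidesmosome genes fell at 2dpa, when 2 of 33 members rose and 23 fell (2 and 24 adjusted over the list alone), with camera adjusted p = 1.94e-05, and adjusted p = 0.392 with an estimated correlation. col17a1a (-7.04 ± 0.37) and cldn1 (-2.51 ± 0.21) fell. Of glycolysis genes at 2dpa 3 of 24 members rose and 17 fell (3 and 17 adjusted over the list alone), with camera adjusted p = 0.00139, and adjusted p = 0.314 with an estimated correlation. ENO1 (-3.43 ± 0.25) and ALDOC (-3.61 ± 0.29) fell. Of immediate early and heat shock genes 6, 1 and 2 of 33 members rose and 21, 30 and 28 fell at 1, 2 and 4dpa (6, 2 and 2 rose and 23, 30 and 29 fell adjusted over the list alone), with camera adjusted p = 0.0189, 2.26e-10 and 6.61e-10, and adjusted p = 0.577, 0.329 and 0.331 with an estimated correlation. CEBPD (-5.22 ± 0.35) and FOSL1 (-4.34 ± 0.31) fell at 2dpa.

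Between 1dpa and 4dpa enam rose in basal cells from 0 to 3619 ± 1068 CPM (at least 4873-fold higher, adjusted p = 3.16e-08), COL10A1 from 0 to 924 ± 530.3 CPM (at least 1244-fold higher, adjusted p = 1.04e-06), scpp5 from 0 to 133 CPM (at least 179-fold higher) and angptl7, a secreted angiopoietin-like gene, from 0 to 172 CPM (at least 231-fold higher). Hematopoietic cells of 4dpa read 852 CPM of enam and 249 CPM of COL10A1. For osteoblast and mineralisation genes 4 of 10 members rose and 1 fell (4 and 1 adjusted over the list alone), with camera adjusted p = 0.556, and adjusted p = 0.769 with an estimated correlation. HSPA2, a chaperone, fell from 516 ± 85.5 to 6.13 ± 3.13 CPM (log2 fold change -6.51 ± 0.39, adjusted p = 1.10e-07) and hsp70.1 from 71.3 ± 23.4 to 1.05 ± 0.724 CPM (log2 fold change -6.43 ± 0.41, adjusted p = 1.95e-07). The secretory-lineage genes AGR2 and muc5.2 fell from 173 to 1.203 CPM (log2 fold change -6.46 ± 0.94) and from 53.2 to 0 CPM (at least 199-fold lower). fgf24 rose (count ratio 190.4, interval 34.2 to 7522), and INHBA (ENSDARG00000012671) fell (log2 fold change -3.35 ± 0.25). Of 11057 genes, 1493 rose and 586 fell. For immediate early and heat shock genes 2 of 33 members rose and 13 fell (2 and 15 adjusted over the list alone), with camera adjusted p = 3.37e-08, and adjusted p = 0.3697 with an estimated correlation. Interferon response genes rose: 30 of 34 members rose and 0 fell (32 and 1 adjusted over the list alone), with camera adjusted p = 3.18e-16, and adjusted p = 0.240 with an estimated correlation. mxc (5.14 ± 0.39), PSMB9 (2.67 ± 0.25) and tapbp.1 (2.44 ± 0.25) rose. For antigen presentation by MHC class II 7 of 10 members rose (8 adjusted over the list alone), with camera adjusted p = 1.50e-05, and adjusted p = 0.352 with an estimated correlation. cd74b (4.93 ± 0.41) and ifi30a (2.12 ± 0.22) rose. For G2/M phase genes 25 of 30 members rose (27 adjusted over the list alone), with camera adjusted p = 1.62e-10, and adjusted p = 0.431 with an estimated correlation. Basal 1dpa values lean on fin 2, since fin 1 gave 34 cells: without fin 2, 1256 genes were called at 1dpa and 227 between 1dpa and 4dpa. With all libraries, DESeq2 called 785 higher and 339 lower between 1dpa and 4dpa. Without fin 2 and1, which rose at 1dpa to 1.05 CPM, went to -2.95, and mmp13a and WNT5A between 1dpa and 4dpa to 0.18 and -0.26. The cells came from different clusters by stage: preinjury 99.9% in cluster 3, 1dpa 47.7%, 26.04% and 22.3% in clusters 15.6, 15.2 and 15.5, 2dpa 98.7% in cluster 13, and 4dpa 72.4% in cluster 11. Cluster 15.2 is led by hsp70l, hsp70.1 and HSPA2, and 113 of its 119 cells of 1dpa came from fin 2, so the fall of these genes is also a change of cluster. At least 99.3% of called genes kept their direction within single lanes.

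**Figure D2:**
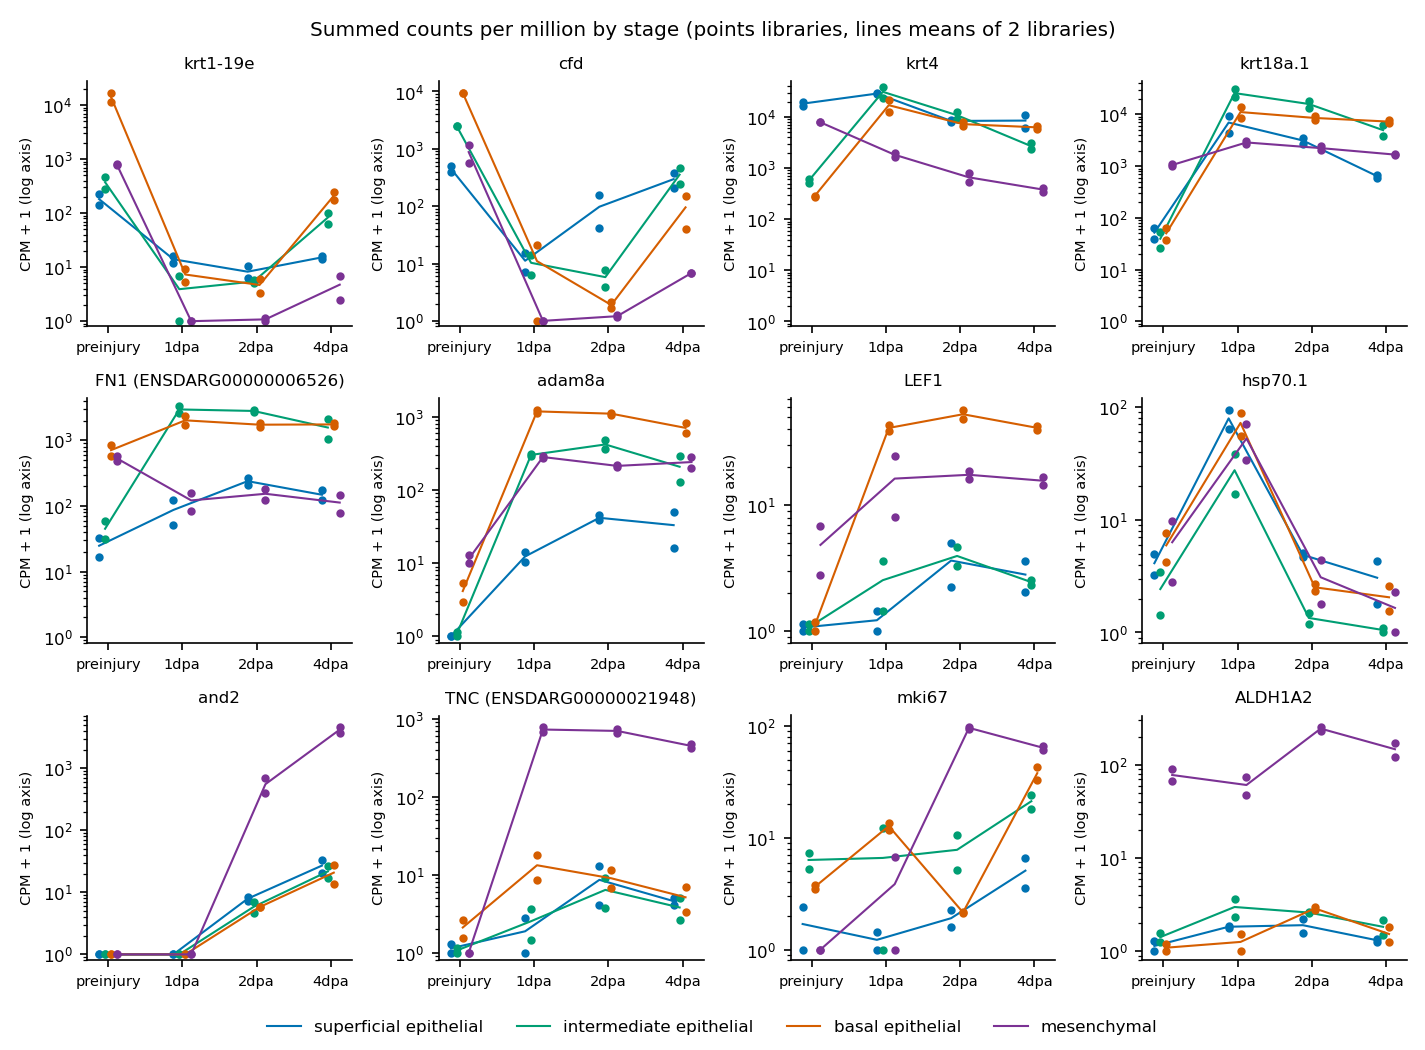
CPM + 1 on a log axis for 12 genes by stage, with points for libraries and lines through the mean of 2 libraries, coloured by class. krt1-19e falls to 6.32 CPM in basal cells at 1dpa, while and2 climbs to 4195 CPM in mesenchymal cells at 4dpa.

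In mesenchymal cells TNC (ENSDARG00000021948), tenascin C of remodelling stroma, rose from 0 to 724 ± 85.7 CPM (at least 215-fold higher, adjusted p = 4.09e-08) at 1dpa. TPH1 (ENSDARG00000036082), the enzyme of serotonin synthesis known from the distal blastema, rose from 0 to 729.5 ± 27.3 CPM (at least 217-fold higher, adjusted p = 2.93e-08). spp1, osteopontin, rose from 0 to 253 ± 199 CPM (at least 75.1-fold higher, adjusted p = 0.00426), and CHST11, a chondroitin sulfotransferase, from 0 to 126 CPM (at least 37.4-fold higher). HPD and TAT, enzymes of tyrosine breakdown, fell from 2595 ± 458 to 0 CPM (at least 755-fold lower, adjusted p = 3.25e-06) and from 1469.8 to 0 CPM (at least 428-fold lower). mamdc2b, a matrix gene, fell from 1048 to 0 CPM (at least 305-fold lower), and dap1b from 960.5 to 0 CPM (at least 279-fold lower). Of 9600 genes tested, 1275 rose and 2273 fell at 1dpa, 1980 and 2579 at 2dpa, and 1895 and 2348 at 4dpa. The median log2 fold change of all genes was -0.34 at 1dpa, and at 4dpa it was 0.06 with TMM and -0.04 with DESeq2 scaling. DESeq2 called 1630 of 4294 genes higher at 2dpa and 1495 of 4010 at 4dpa. Without the low-count filter more genes rose than fell, with 2669 of 5313 and 2576 of 4912 higher.

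At 2dpa and2, the partner of and1 in unmineralised ray fibrils, rose in mesenchymal cells from 0 to 554 ± 219 CPM (at least 164-fold higher, adjusted p = 5.81e-07). CDK1, the mitotic kinase, rose from 0 to 134 ± 11.3 CPM (at least 39.8-fold higher, adjusted p = 1.88e-07), TNC from 0 to 695 CPM (at least 206-fold higher) and TPH1 from 0 to 409 CPM (at least 121-fold higher). HPD fell from 2595 to 0 CPM (at least 15629-fold lower), mamdc2b from 1048 to 0.0422 CPM (count ratio 18939, interval 3399 to 748054), krt1-19e from 786 to 0.0803 CPM (count ratio 14194, interval 2548 to 560645) and ucmaa, a cartilage matrix gene, from 516 to 0.123 CPM (count ratio 4662, interval 1290.5 to 38492). At 4dpa and2 rose from 0 to 4195 ± 635 CPM (at least 1246-fold higher, adjusted p = 4.76e-08), COL10A1 from 0 to 412 CPM (at least 122-fold higher) and the TNC copies from 0 to 445 CPM (at least 132-fold higher) and, for ENSDARG00000078362, from 0 to 122 CPM (at least 36.2-fold higher). Hematopoietic cells of 4dpa read 109 CPM of and2 and 249 CPM of COL10A1. acta2, the smooth muscle actin, fell from 604 to 0.131 CPM (count ratio 3539, interval 979.7 to 29223) and pln1, a regulator of the muscle calcium pump, from 102 to 0.123 CPM (count ratio 1194, interval 214 to 47169). Pericyte and smooth muscle markers summed to 5528 CPM in preinjury and 494 CPM in 4dpa mesenchymal cells. soul5 fell from 87.7 to 0 CPM (at least 343-fold lower) and TIMP4 from 191 to 0.0653 CPM (count ratio 2243, interval 403 to 88612).

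Fixed genes in mesenchymal cells are given whatever their value. ALDH1A2, the retinoic acid enzyme of the blastema, rose at 2 and 4dpa, from 76.8 CPM to 59.8, 243 and 146 CPM (log2 fold changes -0.20 ± 0.32, 1.69 ± 0.25 and 0.95 ± 0.26). mki67 rose, from 0 CPM to 2.85, 95.1 and 62.7 CPM (4 against 0 counts, at least 28.2-fold higher and at least 18.6-fold higher), and PCNA, from 25.03 CPM to 70.7, 262 and 164 CPM (log2 fold changes 1.89 ± 0.55, 3.40 ± 0.46 and 2.72 ± 0.47). mmp13a rose at 2 and 4dpa, from 6.35 CPM to 10.8, 119 and 813 CPM (log2 fold changes 0.80 ± 1.00, 3.93 ± 0.62 and 6.71 ± 0.55). So did MMP9 (count ratio 2.77, interval 0.949 to 13.5, count ratio 16.7, interval 5.71 to 80.9 and count ratio 8.38, interval 2.87 to 40.6) and LEF1 (count ratio 4.54, interval 1.55 to 22.03, count ratio 4.89, interval 1.67 to 23.7 and count ratio 4.36, interval 1.49 to 21.1). At 2 and 4dpa and1 rose as well (0 against 1 counts, count ratio 268, interval 48.2 to 10598 and count ratio 2043, interval 367 to 80679). col1a1a fell at 1dpa and rose later, from 945 CPM to 464, 1628 and 5948 CPM (log2 fold changes -0.99 ± 0.24, 0.78 ± 0.22 and 2.65 ± 0.23). msx1b, a homeobox gene of the distal blastema, fell at 1dpa (-0.94 ± 0.25, -0.01 ± 0.22 and 0.19 ± 0.22), and WNT5A at 1 and 2dpa (-1.21 ± 0.36, -0.83 ± 0.26 and 0.61 ± 0.25). FN1 (ENSDARG00000006526) fell (-2.31 ± 0.37, -1.79 ± 0.31 and -2.23 ± 0.31), while FN1 (ENSDARG00000019815) rose at 1dpa (1.81 ± 0.36, 0.28 ± 0.35 and -0.42 ± 0.35). JUNB fell in its ENSDARG00000074378 (-2.64 ± 0.24, -4.23 ± 0.26 and -4.05 ± 0.26) and ENSDARG00000104773 copies (-3.47 ± 0.28, -4.08 ± 0.27 and -3.89 ± 0.27). Epithelial genes fell too, krt4 from 7870.3 CPM to 1824, 659 and 379 CPM (log2 fold changes -2.10 ± 0.25, -3.58 ± 0.26 and -4.38 ± 0.27), and epcam (-3.97 ± 0.37, -2.90 ± 0.30 and -3.29 ± 0.31). cdh1 fell (count ratio 27.6, interval 7.65 to 228, log2 fold change -2.27 ± 0.37 and log2 fold change -1.97 ± 0.37), with TP63 at 1 and 4dpa (count ratio 8.48, interval 2.90 to 41.1, log2 fold change -1.07 ± 0.43 and log2 fold change -1.67 ± 0.46) and AGR2 at 2 and 4dpa (count ratio 3.03, interval 1.04 to 14.7, log2 fold change -3.62 ± 0.81 and log2 fold change -3.10 ± 0.80). krt1-19e fell from 786 CPM to 3.74 CPM at 4dpa. Without krt4, genes that among epithelial classes are high in superficial cells alone summed to 5179 and 3025 CPM in the preinjury mesenchymal libraries, and the matching sums at 4dpa were 293 and 346 CPM. SP7, il1b, tnfa and TPH2 were not tested and read 3.32, 1.23, 0.123 and 0.0653 CPM at 4dpa.

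In mesenchymal cells G2/M phase genes rose at 2 and 4dpa: 1, 29 and 27 of 30 members rose at 1, 2 and 4dpa (0, 30 and 28 adjusted over the list alone), with camera adjusted p = 0.0139, 7.62e-14 and 1.85e-12, and adjusted p = 0.577, 0.314 and 0.314 with an estimated correlation. MAD2L1 (count ratio 101, interval 18.1 to 3982) and hmgb2b (2.42 ± 0.21) rose at 2dpa. Of S phase genes at 2dpa 23 of 26 members rose and 1 fell (24 and 1 adjusted over the list alone), with camera adjusted p = 9.04e-08, and adjusted p = 0.426 with an estimated correlation. RRM2 (count ratio 56.1, interval 19.2 to 272) and RPA2 (2.97 ± 0.35) rose and DUT (-4.46 ± 0.43) fell. Ribosome biogenesis rose: 22, 22 and 21 of 28 members rose and 1, 2 and 2 fell at 1, 2 and 4dpa (24, 23 and 21 rose and 1, 2 and 2 fell adjusted over the list alone), with camera adjusted p = 9.49e-12, 2.38e-07 and 2.32e-06, and adjusted p = 0.383, 0.426 and 0.447 with an estimated correlation. npm1a (2.83 ± 0.23), FBL (2.23 ± 0.22) and NOP10 (2.42 ± 0.26) rose at 1dpa. Of nuclear oxidative phosphorylation genes at 1dpa 36 of 56 members rose and 2 fell (39 and 3 adjusted over the list alone), with camera adjusted p = 3.08e-14, and adjusted p = 0.240 with an estimated correlation. COX7A2 (2.74 ± 0.24) and cycsb (2.198 ± 0.22) rose. Glycolysis passed at 1dpa, when 8 of 22 members rose and 6 fell (8 and 6 adjusted over the list alone), with camera adjusted p = 0.0395, and adjusted p = 0.352 with an estimated correlation. ENO1 (2.85 ± 0.27), LDHA (2.17 ± 0.23) and PKM (1.95 ± 0.22) rose. Immediate early and heat shock genes fell: 5, 0 and 0 of 33 members rose and 23, 28 and 30 fell at 1, 2 and 4dpa (5, 0 and 0 rose and 24, 29 and 30 fell adjusted over the list alone), with camera adjusted p = 2.62e-07, 7.51e-15 and 3.88e-17, and adjusted p = 0.314, 0.240 and 0.240 with an estimated correlation. FOS (-6.16 ± 0.27), BTG2 (-5.00 ± 0.22) and FOSL1 (-4.53 ± 0.22) fell at 4dpa. Of blastema and fin outgrowth signalling genes 7, 12 and 12 of 34 members rose and 9, 6 and 5 fell at 1, 2 and 4dpa (8, 12 and 12 rose and 9, 6 and 5 fell adjusted over the list alone), with camera adjusted p = 0.275, 0.0412 and 0.00396, and adjusted p = 0.566, 0.392 and 0.314 with an estimated correlation. Of fibrillar and provisional matrix genes 6, 9 and 12 of 28 members rose and 14, 9 and 8 fell at 1, 2 and 4dpa (6, 11 and 12 rose and 15, 9 and 8 fell adjusted over the list alone), with camera adjusted p = 0.159, 0.528 and 0.194, and adjusted p = 0.659, 0.828 and 0.684 with an estimated correlation. Of actin cytoskeleton and migration genes at 2dpa 3 of 38 members rose and 27 fell (3 and 28 adjusted over the list alone), with camera adjusted p = 3.14e-06, and adjusted p = 0.240 with an estimated correlation. VIM (-9.29 ± 0.35) fell. Antigen presentation by MHC class II fell at 1dpa, when 7 of 9 members fell (9 adjusted over the list alone), with camera adjusted p = 0.000843, and adjusted p = 0.3297 with an estimated correlation. cd74a (-5.38 ± 0.40) and cd74b (-5.85 ± 0.46) fell. Macrophage markers in these cells summed to 1258 CPM before injury and 46.3 CPM at 1dpa.

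Between 1dpa and 4dpa and2 rose in mesenchymal cells from 0 to 4195 ± 635 CPM (at least 1220.4-fold higher, adjusted p = 1.37e-06) and and1 from 0 to 2292 ± 315 CPM (at least 667-fold higher, adjusted p = 6.14e-07). COL10A1 rose from 0 to 412 CPM (at least 119.8-fold higher) and enam from 0 to 195 CPM (at least 56.8-fold higher), against 249 and 852 CPM in hematopoietic cells. ca9, a carbonic anhydrase induced by hypoxia, fell from 68.4 to 0 CPM (at least 267-fold lower). The chaperones HSPA2, hsp70.3 and hsp70l fell from 351 to 2.25 CPM (log2 fold change -6.97 ± 0.47), from 799 to 8.04 CPM (log2 fold change -6.46 ± 0.50) and from 287 to 2.91 CPM (log2 fold change -6.30 ± 0.58). Glycolysis genes fell: 0 of 22 members rose and 9 fell (1 and 10 adjusted over the list alone), with camera adjusted p = 3.73e-09, and adjusted p = 0.237 with an estimated correlation. ENO1 (-4.12 ± 0.26) and LDHA (-2.35 ± 0.19) fell. For the fibrillar and provisional matrix 16 of 28 members rose and 2 fell (16 and 4 adjusted over the list alone), with camera adjusted p = 2.39e-05, and adjusted p = 0.392 with an estimated correlation. For G2/M phase genes 24 of 30 members rose (29 adjusted over the list alone), with camera adjusted p = 2.16e-15, and adjusted p = 0.295 with an estimated correlation. Here 1042 genes rose and 472 fell, 68.8% higher, against 51.6% of 1399 with DESeq2 and 58.5% of 1493 with RLE scaling, and the median log2 fold change of all genes was 0.31, 0.17 and 0.19 in turn. The 1dpa libraries held 21 and 55 cells, and without fin 2, 1557 genes were called at 1dpa, 393 between 1dpa and 4dpa, and PCNA at 1dpa went to -0.55. Without preinjury fin 1, 2802 genes were called at 4dpa. Preinjury mesenchymal cells lay 99.6% in cluster 7 and 2dpa cells all in cluster 14, with median UMIs per cell of 4331 and 4810.5 against 16634 and 17166, and at least 99.7% of called genes kept their direction within single lanes.

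**Figure D3:**
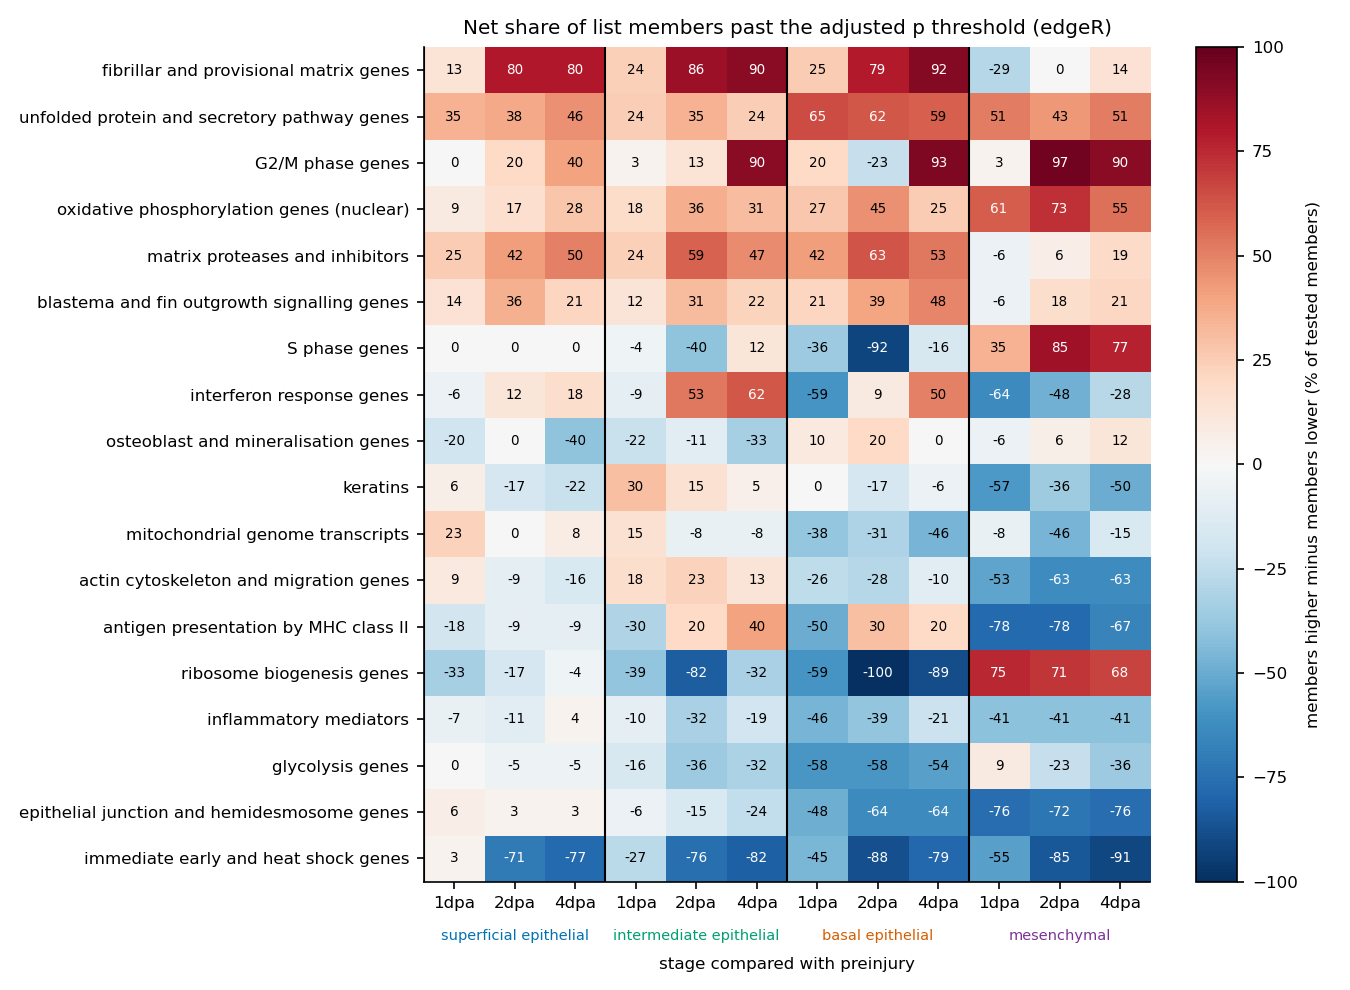
Members higher minus members lower, as a percent of tested members, for 18 gene lists (lines) in 4 classes at 1, 2 and 4dpa against preinjury (columns). Ribosome biogenesis stands at -100% in basal cells at 2dpa and 71.4% in mesenchymal cells.

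The change after injury differed between basal and superficial cells for single genes, and no list was tested on this difference. The log2 difference is the basal change minus the superficial change, ± standard error. It is not given where a class had 0 counts at a stage, and rests on 3 counts or fewer in a group for OGN, PRICKLE1, trim108, sox19a, SLC43A3, LUM and irf1a. At 1dpa it was 8.74 ± 1.83 for OGN (ENSDARG00000044132), a small matrix proteoglycan, and 7.49 ± 0.93 for PRICKLE1 (ENSDARG00000045694), a planar polarity gene. SRPX went from 583 to 261 counts in basal and from 24 to 0 in superficial cells. Neither class alone passed for SRPX (adjusted p = 0.196 and 0.0628). vcana went from 0 ± 0 to 92.9 ± 41.98 CPM in basal and from 0.574 ± 0.812 to 2.07 ± 0.408 CPM in superficial cells. OGN went from 0.0953 ± 0.135 to 73.7 ± 50.7 in basal and from 0.4999 ± 0.511 to 0.393 ± 0.555 CPM in superficial cells. It was -7.02 ± 0.71 for trim108, -7.00 ± 0.73 for sox19a, a SoxB transcription factor, and -6.85 ± 0.48 for krt1-19e. PAQR5 (ENSDARG00000052688) went from 16 to 0 counts in basal and from 1508 to 430 in superficial cells. sox19a went from 11.2 ± 1.29 to 0.132 ± 0.186 CPM in basal and from 37.6 ± 11.01 to 104 ± 21.2 CPM in superficial cells. At 2dpa the difference was 9.12 ± 0.59 for the transporter SLC43A3 (ENSDARG00000057949), 7.33 ± 0.34 for krt97 and 6.13 ± 1.02 for LUM, another matrix proteoglycan. emilin1b went from 0 to 3266 counts in basal and from 2 to 9 in superficial cells. krt97 went from 86.3 ± 1.24 to 9602 ± 186 CPM in basal and from 4453 ± 629.6 to 3250.2 ± 526 CPM in superficial cells. It was -10.94 ± 0.46 for cfd, -8.14 ± 0.46 for SAA2, an acute phase gene, -7.96 ± 1.29 for ccl19b and -7.64 ± 0.38 for the carbonic anhydrase CA6. SAA2 went from 25.9 ± 31.9 to 3.56 ± 0.372 CPM in basal and from 9.52 ± 11.4 to 392 ± 22.9 CPM in superficial cells. At 4dpa the difference was 8.29 ± 0.60 for SLC43A3, 5.72 ± 0.33 for krt97 and 5.62 ± 0.31 for krt4, and emilin1b went from 0 to 856 counts in basal and from 2 to 18 in superficial cells. For ccl19b, cfd, SAA2 and irf1a, an interferon regulatory factor, it was -8.62 ± 0.73, -6.27 ± 0.37, -6.14 ± 0.44 and -5.39 ± 0.86. Adjusted p of these 24 edgeR differences ran from 4.70e-20 to 0.0241. Of 11332 genes tested, 491 had a higher and 1242 a lower change in basal cells at 1dpa, 947 and 1666 at 2dpa, and 730 and 1399 at 4dpa. Without 1dpa fin 2, 690 differences were called at 1dpa, and without 2dpa fin 1 or fin 2, 1648 or 1598 at 2dpa. With all libraries, DESeq2 called 429 higher and 913 lower at 4dpa.

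No hematopoietic change against preinjury can be given, because preinjury fin 2 held 1 hematopoietic cell and 1dpa fin 1 held 16. Macrophage markers summed to 39943 CPM of this class at 2dpa and 52822 CPM at 4dpa. Over all 252 list tests camera called 143, 83 higher and 60 lower, and none of the 143 had a median or mean of opposite sign to its test. Signs of median, mean and test differed in 27 of the 109 other tests. With an estimated correlation 0 of 252 were called, the adjusted p running from 0.237 to 0.999 and 38 having an unadjusted p under 0.05, while fry called 150.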

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

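The tests on epithelial transcripts in mesenchymal cells and on immediate early genes were chosen after the result was seen, and those on enamel-type genes before. The responses of basal and superficial epithelial cells differed by an interaction test for 1733 genes at 1dpa, 2613 at 2dpa and 2129 at 4dpa. EGFP, which no comparison used, read 214 CPM in superficial epithelial cells, with 55.9% of cells holding a UMI of it against 0.581% of hematopoietic cells, and the sequence its counts were matched to is not given in the sources used here, while SP7 itself read 1.38 CPM in superficial and 1.72 CPM in mesenchymal cells.

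Epithelial transcripts were far higher in preinjury than in regenerating mesenchymal cells. For genes found in superficial cells alone among the epithelial classes, free RNA or droplets shared with superficial cells could account for it: these genes stood near a common ratio to their superficial level, the upper quartile being at most 1.62 times the lower. krt4 argues against that explanation for itself, since its mesenchymal level over the superficial level was at least 6.10 times the upper quartile of those genes. A different mix of stromal cells before injury, such as cells of cluster 7 with pericyte markers, stays open and was not tested. The changes of keratins and junction genes in mesenchymal cells therefore do not show that stromal cells stopped expressing them.

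Immediate early and heat shock genes were lower at 2 and 4dpa than before injury in 4 classes by camera, though with an estimated correlation the adjusted p ran from 0.240 to 0.370. Free RNA from a single source cannot be told apart from expression: it adds equal UMIs per cell to the 3 classes other than the source, and for the 4 possible sources these classes differed by 1.04 to 1.16-fold in preinjury fin 1 but 1.64 to 2.58-fold in fin 2. A few genes do not carry it, since at least 71.0% of tested members fell past the threshold in each class at 2 and 4dpa. Handling of the preinjury fins before lysis cannot be told apart from injury: preinjury, 2dpa and 4dpa fins of a stage differed by up to 1.60-fold against 2.83 to 13.6-fold between preinjury and later stages, but fins of a stage can share their handling. A lower resting level of these genes in regenerating tissue stays open as well and was not tested.

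enam, COL10A1 (ENSDARG00000054753), scpp5 and scpp7 were read at 4dpa outside basal cells and the unnamed cluster 10. There the median over these 4 genes did not exceed the hematopoietic level in CPM, which met the prediction made for free RNA. It stood at 0.436 and 0.890 of that level in superficial, 0.321 and 0.449 in intermediate and 0.199 and 0.369 in mesenchymal cells of the 2 libraries. These ratios cannot decide, because free RNA adds equal UMIs per cell and so more CPM to cells with fewer UMIs. Median UMIs were 4969 and 5274 in hematopoietic cells, against 7840.5 and 8325.5 in superficial cells. In intermediate cells they were 9677 and 12374.5, and in mesenchymal cells 11699 and 11438. Cluster 10 held the transcripts, with enam at 57753 and 51960 CPM against 2864 and 4374 CPM in basal cells. COL10A1 taken alone stood above the hematopoietic level in mesenchymal cells, at 346 and 477 CPM against 281 and 217 CPM. scpp5 stood at 3.10 times the hematopoietic level in superficial cells of fin 1 and 1.88 times in intermediate cells of fin 2. At 2dpa superficial cells already read 56.2 CPM of COL10A1 and 97.5 CPM of enam against 5.81 and 29.1 CPM in hematopoietic cells, so expression by some cells of each class stays open.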

How the results depend on the processing

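Clusters not split again, clusters led by another class's markers kept, top genes ranked by the naming fold, the fit without the 1dpa libraries and the hematopoietic comparison were tests chosen after seeing the data. Of 441 gene values called in the main test, 8407 values under the alternatives kept direction and call in 8135 cases, lost the call in 268 and turned in 4. The 4 were all without 1dpa replicate 2: and1 in basal cells at 1dpa (-2.95), mmp13a (0.18) and WNT5A (-0.26) in basal cells at 4dpa against 1dpa, and PCNA in mesenchymal cells at 1dpa (-0.55), where the other 1dpa library had 34 basal and 21 mesenchymal cells. Over all libraries left out, these ran from -2.95 to 6.87, -1.67 to 0.18, -0.26 to 1.30 and -0.55 to 2.60. A lone library is assumed to vary like the other groups. Apart from the fixed genes, the 441 were picked from the same data for extreme folds or low adjusted p, which favours keeping the call. Values that an alternative could not give were not counted as lost. Of the 441, 351 had a value at resolution 1.0 and 391 under the ranking by the naming fold. DESeq2 called 1124 genes in basal cells at 4dpa against 1dpa and 1342 basal against superficial differences at 4dpa. Without a filter 1397 genes were called in superficial cells at 1dpa and 468 in hematopoietic cells. With clusters not split again, 2229 were called in superficial cells at 2dpa. In hematopoietic cells the fin number was the lane, so the block and the lane covariate were the same fit there, with 48 calls. They moved no other count they were run on by more than 1.5-fold, the basal against superficial differences not being among these. With the lane, calls at 1dpa were 603 against 904 in superficial and 2066 against 2242 in intermediate cells. In basal cells they were 4257 against 4601, and in mesenchymal cells 3158 against 3548. The stricter cell filter and doublet removal moved no count by more than 1.5-fold. The cause was not tested. Leaving out each library in turn, calls ran at 1, 2 and 4dpa from 310 to 1023, 405 to 1499 and 897 to 1548 in superficial, 621 to 2319, 2822 to 4643 and 2578 to 3866 in intermediate, 1256 to 4771, 4645 to 6586 and 4026 to 5699 in basal, and 1557 to 3253, 3058 to 4959 and 2802 to 4632 in mesenchymal cells. At 4dpa against 1dpa they ran from 227 to 2431 in basal and 393 to 1672 in mesenchymal cells, and at 4dpa against 2dpa from 26 to 72 in hematopoietic cells. Basal against superficial differences ran from 690 to 1835, 1598 to 2743 and 1438 to 2293. The log2 ratio of shares in regenerating over preinjury fins ran from -1.44 to -0.60 for superficial, -0.26 to 0.0525 for intermediate, -0.47 to -0.11 for basal, 0.38 to 1.05 for mesenchymal and 1.54 to 6.21 for hematopoietic cells. The exact permutation tests were over the 4 stages and not on these ratios. Without 1dpa replicate 2 the superficial ratio was -0.84. The ratio was 7.64 at resolution 1.0 and 6.87 with a class per cell for intermediate cells. For basal cells it was 0.12 without the second split and -1.42 under the ranking by the naming fold. For mesenchymal cells it was 4.45 with a class per cell, where the test over the stages gave p = 0.00952 (exact permutation test, adjusted p = 0.0571). No hematopoietic contrast with preinjury, mucosal-like share by cluster or intermediate contrast at resolution 1.0 can be given. Nor can 1dpa intermediate values without the second split or 2dpa basal values with the naming-fold ranking. Of 143 list calls, fry kept 119, the block 140 and no filter 138, and with an estimated correlation 0 were called. Leaving out libraries gave 139 to 150 calls. Blocking on fin number, which the labels do not call a pair, gave 802, 1262 and 1485 calls in superficial, 2292, 4553 and 3860 in intermediate, 4373, 5917 and 5246 in basal and 3322, 4312 and 4012 in mesenchymal cells. Differences between fins 1 and 2 correlated across genes from -0.41 to 0.12 over 6 pairs of stages, above 0.1 in 1. The 1dpa fin 1 sums held 172226 UMIs in basal and 133689 in mesenchymal cells, the smallest of their class.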

Other observations

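No explanation was tested for the values given here, and the comparison of hematopoietic cells was chosen after seeing the data. In hematopoietic cells, whose share of macrophages was not measured, 18 of 7456 genes tested rose and 12 fell between 2dpa and 4dpa (edgeR). Without the low-count filter 283 rose and 185 fell, with the block or the lane covariate 32 rose and 16 fell, and without 4dpa fin 2 49 rose and 23 fell. mfap4.7, of a microfibril-associated family that marks zebrafish macrophages, rose from 0 to 247 ± 25.2 CPM (at least 253-fold higher, adjusted p = 0.00213). Its paralogs mfap4.8, mfap4.6 and mfap4.11 rose from 0.347 to 214 CPM (count ratio 656, interval 118 to 25917), from 0.654 to 282 CPM (count ratio 433, interval 119.8 to 3573) and from 0.693 to 122 CPM (count ratio 188, interval 51.98 to 1550.5), and reads of such near-identical genes can be assigned to the wrong copy. lgals2b, a galectin, fell from 81.9 to 0.377 CPM (count ratio 176, interval 31.5 to 6938), and apoc1, an apolipoprotein of lipid-loaded macrophages, from 102 ± 6.64 to 2.497 ± 1.804 CPM (log2 fold change -5.15 ± 0.36, adjusted p = 0.00303). The ferritin gene fthl28 fell from 3151 ± 849 to 329 ± 85.01 CPM (log2 fold change -3.26 ± 0.26, adjusted p = 0.00484) and gsto2, a glutathione transferase, from 558 ± 167 to 144 ± 3.86 CPM (log2 fold change -1.96 ± 0.22, adjusted p = 0.0274). The antigen presentation genes cd74a and cd74b rose (log2 fold change 1.75 ± 0.16 and log2 fold change 1.22 ± 0.11).

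Some cells got no class. Cluster 10 had 11 of 16 basal markers up and was kept out of the basal class by 1 marker of another class among its top 10 genes. Led by scpp7, COL10A1 (ENSDARG00000054753), enam and scpp5, it made up 1.47 ± 0.787% of cells at 2dpa and 10.1 ± 0.108% at 4dpa, and 0% before injury and at 1dpa. Cluster 15.1, with 8 of 16 basal and 7 of 11 intermediate markers up and led by the neutrophil chemokine gene cxcl8b.1 and mmp13a, held 14.5 ± 0.641% of cells at 1dpa. A cluster of interferon response genes (isg15, RSAD2, mxb) held 0.847 ± 0.396% at 2dpa and 1.29 ± 0.168% at 4dpa.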
